A study of Rattus norvegicus with 8 samples.

How the data were processed

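Total RNA of the pituitary was labelled with Cy3 and hybridised to 8 Agilent whole-genome rat arrays, 1 colour per array, per the labels' protocols. Groups were taken from the agent given in the labels: 4 control and 4 TCDD samples. Images were quantified with Agilent Feature Extraction 10.7.1.1, per the file headers, which gives each spot's mean intensity, local background intensity, a processed intensity after background subtraction and detrending (with surrogate values for dim spots), and flags. These deposited intensities are linear and were computed for each array on its own, per the file headers. The headers also name rn4 as the build of the probe coordinates.

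A table of values for the same arrays was deposited too. Its intensities are linear, the sorted values of each column equal those of the first exactly in 99.3% of ranks or more, and each column's median is 56.3. Within each array its ranks follow the processed intensities averaged over a probe's spots (Spearman correlation 1 after rounding, across probes, which are not replicates). The authors thus deposited intensities with 1 shared distribution. How spots were combined, and whether the table was scaled further, are not given in the sources used here. It served as an alternative.

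Of 44254 spots per array, 42877 were not controls, and these held 30367 probes, 1390 of them on 10 spots each. Gene names were updated through a RefSeq table of the GRCr8 assembly, used for names only. By accession 17998 probes were matched, by symbol 2662 and by an older symbol 559, and 9148 kept the name in the files. Log2 of the processed signal was taken minus each array's 75th percentile of it over non-control spots. Spots marked as outliers were set to missing, and log2 values of a probe's spots were averaged. A probe left with too few arrays in a group was not used. A probe counted as well above background on an array where at least as many of its spots were marked so as were not, and was kept if that held on 4 or more arrays. Of a gene's kept probes the one with the highest mean over all arrays was used. Another kept probe had the opposite sign for Hsp90ab1, Mbp, Ptprn2 and Vwf among the genes the rule below takes.

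Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, group as the only term, two-sided, with Benjamini-Hochberg adjustment over the 17361 genes and a threshold of 0.05. A gene not well above background on any array of 1 group has only a bound there. Its fold is given as "at least", from the mean of the brighter group against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background. Lists of genes were tested with camera (correlation between genes set to 0.01), adjusted over the 27 lists with 3 or more measured members. Camera with an estimated correlation and fry were alternatives: with an estimated correlation 0 lists passed, and by fry AhR target genes and the NRF2 response did. Fry tests whether a list's genes move on balance 1 way and does not set them against other genes. Named genes were also given an exact two-sided permutation test over 70 assignments, with 0.029 as the smallest p.

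The gene lists and the tests of genes and lists, other than those said to be chosen later, were fixed before the data were examined. So was the rule for named genes. Tests of explanations, such as liver RNA or red blood cell content, name the pattern they explain. They are not counted as fixed before the data were examined. The rule for named genes takes genes with a symbol, past the threshold and with groups that do not overlap: up to 12 rises and 12 falls by size, filled to 12 in each direction by the smallest unadjusted p among non-overlapping genes that do not pass. It adds all measured hormone and AhR target genes and up to 4 members of each other list. Genes known only by an accession or probe number were counted and not named, except the transcript that the files describe as Tiparp.

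The fit was tested on simulated data with the means and spreads of the 17361 genes and 200 changed genes. Of 50 genes changed 1.5-fold it called 60%, of 50 changed 2-fold 86%, of 50 changed 4-fold 98% and of 50 changed 8-fold 100%. There were 9 calls among unchanged genes. These shares hold for 200 changed genes. The adjustment is stricter where fewer genes pass, as with the 14 called in the real data, so there the shares are likely lower. Of 27 simulated lists the 1 that was shifted by 0.5 was found, and 0 others. The simulated genes varied independently, so this does not test camera on lists whose genes move together. The erythrocyte markers, for example, had an estimated correlation of 0.94. Alternatives covered background correction with normexp (offset 50) and quantile normalization, quantile normalization alone, median centring, the filter, the probe summary, outlier spots, the variance model, array weights, the deposited table, the replicate number as a block, and each array left out in turn. A fit with slide as a block was not possible, since each slide holds 1 group. Figures were drawn with matplotlib 3.10.9. In the check for arrays that stand apart within their group, 1 named gene was left out and is not reported here.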

Results

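Messenger RNA was measured in whole pituitary tissue of Wistar rat dams that were nursing, on postpartum day 7. The 8 samples formed 2 groups: 4 control dams and 4 dams exposed to TCDD, a dioxin that binds the aryl hydrocarbon receptor (AhR), a ligand-activated transcription factor. The comparison asks which pituitary transcripts differ in mothers after dioxin exposure. The labels used here give neither the dose nor the day of exposure. The series' design text gives 4 rats per group, and the labels do not say more about how the samples were taken, so p-values measure the spread between these samples. Each sample was hybridised to 1 single-colour Agilent whole-genome rat array. The 75th percentile of signal per array lay between 765 and 932, and 71.1% to 73.9% of spots were well above background. After the filter, 17361 genes were tested, 12461 of them with a gene symbol. The number of arrays limits the precision. All 4 control arrays lay on slide 1 and all 4 TCDD arrays on slide 2, so slide and group cannot be told apart in any value below.

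The largest rises in fold among the genes that passed were in 2 drug-metabolising enzymes that AhR induces, while the smallest adjusted p was that of Bpifb9a, given with the other genes. Cyp1a1, a cytochrome P450 that oxidises aromatic hydrocarbons, was at least 7.28-fold higher on the TCDD arrays (limma, adjusted p = 0.028), with a measured log2 signal of -7.40 ± 0.58 (SD, n = 4) in controls and -3.42 ± 0.70 (SD, n = 4) after TCDD. Cyp1a2, its close relative, was at least 2.88-fold higher (adjusted p = 0.029), at -8.41 ± 0.13 in controls and -4.76 ± 0.89 after TCDD. Neither gene was well above background on any of the 4 control arrays, and both were on all 4 TCDD arrays. For this reason the folds are lower bounds, and the fitted log2 changes of 3.98 (SE 0.39) and 3.65 (SE 0.39) are not used as sizes. The probe of Cyp1a1 lies on chromosome 8 from 61468133 to 61468192, and that of Cyp1a2 on chromosome 8 from 61439236 to 61439295, in the rn4 build named by the files. The exons the probes fall in were not determined here. Leaving out 1 array ended the call of Cyp1a1 for control replicates 1, 2 and 3 and TCDD replicates 1, 2 and 4 (adjusted p between 0.079 and 0.13), and that of Cyp1a2 for each control replicate and TCDD replicates 1 and 2 (0.067 to 0.15). With quantile normalization both stood at an adjusted p of 0.0501, over a range of 0.020 to 0.32 across all settings. The bounds were computed with the 75th percentile scaling alone. Normexp background correction and quantile normalization together are called normexp from here on. With normexp the fitted changes were 1.04 for Cyp1a1 (adjusted p = 0.22) and 0.57 for Cyp1a2 (0.26). Normexp as run here adds a fixed offset to the corrected intensities, which by arithmetic makes the log2 changes of dim genes smaller. For dim genes a smaller size with normexp, here and below, thus partly follows from the setting.

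Of the 11 AhR target genes measured, 9 were higher and 2 lower on the TCDD arrays, 2 passed over all genes tested and 6 passed adjusted over the list alone. The other 4 that rose on that narrower count were Nqo1, a quinone reductase, by 2.13-fold (log2 1.09, SE 0.21; 0.72 with normexp), Ahrr, the repressor of AhR, by at least 1.68-fold (fitted log2 change 0.10 with normexp), Aldh3a1, an aldehyde dehydrogenase, by 1.68-fold (log2 0.75, SE 0.20), and Cyp1b1, another cytochrome P450, by 1.28-fold (log2 0.36, SE 0.11). Over all genes their adjusted p-values by limma were 0.18, 0.20, 0.30 and 0.32. Ahrr was well above background on 0 of 4 control arrays and 4 of 4 TCDD arrays. The exact two-sided permutation p was 0.029 for Cyp1a1, Cyp1a2, Nqo1 and Ahrr, the smallest that 4 against 4 arrays can give, and 0.057 for Aldh3a1 and Cyp1b1. The remaining 5 members did not pass: the log2 change was 0.16 (SE 0.27) for Slc7a5, 0.08 (SE 0.06) for Nfe2l2, 0.03 (SE 0.05) for Ugt1a6 and -0.21 (SE 0.13) for Xdh. With normexp Slc7a5 and Ugt1a6 stood below 0. Tiparp, found through the files' own description of transcript ENSRNOT00000015387, differed by -0.08 (SE 0.08). As a set the list was shifted up (camera, adjusted p = 1.16e-04; median log2 change 0.36, also with the 3 background-limited genes at their bounds). That call was lost with an estimated correlation (adjusted p = 0.12), with only members well above background on all 8 arrays (0.13), and without the 3 members that no control array measured (0.14, chosen after the data were seen). The last 2 are nearly the same check, since both leave out Cyp1a1, Cyp1a2 and Ahrr, and a rise from below background itself decides that. With normexp the list passed at a median of 0.10 (adjusted p = 0.0071). Gsta2, the remaining member, was not measured.

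**Figure D1:**
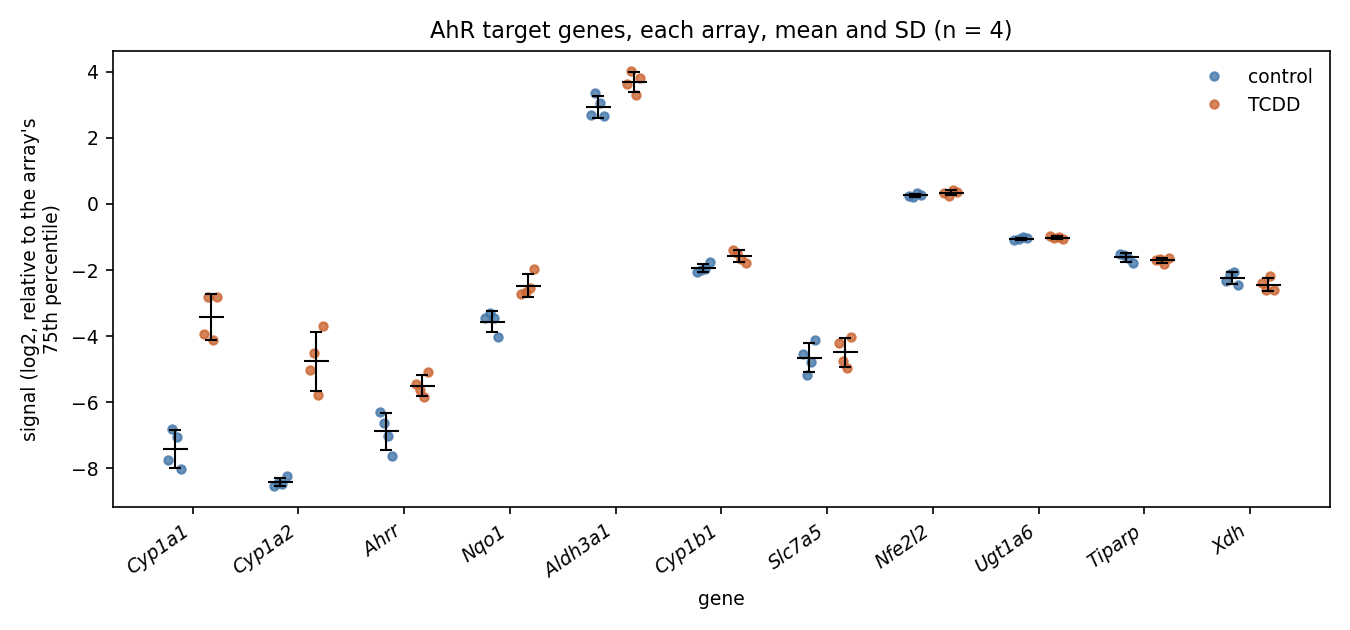
Signal of the 11 measured AhR target genes on each array (points; log2, relative to the array's 75th percentile), with the mean and SD of 4 control and 4 TCDD arrays. For Cyp1a1, Cyp1a2, Nqo1 and Ahrr every TCDD array lies above every control array, while Ugt1a6 and Nfe2l2 differ by 0.03 and 0.08.

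The genes for the anterior pituitary hormones gave no call. Prolactin (Prl), the hormone that drives milk production, differed by -0.0026 on the log2 scale (SE 0.07), with a 95% confidence interval from -0.16 to 0.15 and a control level of 8.17 ± 0.05 (SD, n = 4). Growth hormone (Gh1) differed by -0.08 (SE 0.06), Pomc, the precursor of ACTH, by -0.0046 (SE 0.07), and Cga, the subunit shared by the glycoprotein hormones, by -0.0066 (SE 0.11). The sign for Prl, Pomc and Cga depended on the scaling, Prl lying between -0.03 and 0.05 over all settings. Lhb and Tshb, the beta subunits of luteinising and thyroid-stimulating hormone, differed by 0.05 (SE 0.14) and 0.18 (SE 0.29), and over all settings by -0.09 to 0.14 and by -0.13 to 0.36. Fshb, the beta subunit of follicle-stimulating hormone, was at 1.55 ± 0.43 in controls and 0.84 ± 0.36 after TCDD, a log2 change of -0.71 (SE 0.25) that did not pass (limma, adjusted p = 0.38). Its exact two-sided permutation p was 0.057. The list was not shifted as a set (camera, adjusted p = 0.34). Prl, Gh1, Pomc and Cga were among the 17 brightest of all genes tested, and no spot was flagged as saturated. The flag does not show whether signals this bright still follow the amount of RNA in proportion. That was not tested, so small changes here may be understated.

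**Figure D2:**
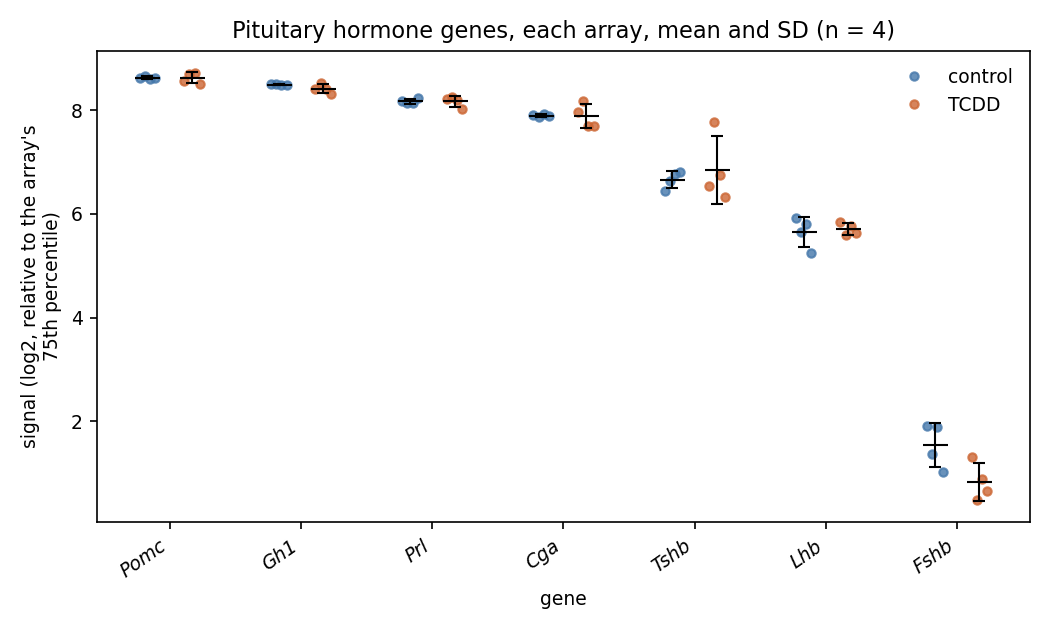
Signal of the 7 pituitary hormone genes on each array (points; log2, relative to the array's 75th percentile), with the mean and SD of 4 control and 4 TCDD arrays. The groups overlap for each gene, with Fshb at a mean of 1.55 in controls and 0.84 after TCDD.

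Across all genes, 14 passed an adjusted p of 0.05: 10 were higher and 4 lower after TCDD, and 9 of them carry a gene symbol. Besides the cytochromes, 4 named genes rose: C10h17orf50 by 2.00-fold (log2 1.00, SE 0.11), Zic2, a zinc-finger transcription factor, by 1.55-fold (log2 0.63, SE 0.08), Begain by 1.47-fold (log2 0.55, SE 0.07) and Alox12b, a lipoxygenase, by 1.41-fold (log2 0.49, SE 0.06). Their adjusted p-values lay between 0.029 and 0.050. The 3 named genes that fell were Bpifb9a, 2.28-fold lower (log2 -1.19, SE 0.08, adjusted p = 0.0079), Itgb7, an integrin subunit of lymphocytes, 1.91-fold lower (log2 -0.94, SE 0.11, adjusted p = 0.042), and Acss3, an acyl-CoA synthetase, 1.78-fold lower (log2 -0.83, SE 0.08, adjusted p = 0.028). With normexp these 7 changes were smaller and none passed, Bpifb9a at -0.32 and C10h17orf50 at 0.18. The offset that normexp adds itself makes changes of dim genes smaller, and its share in this was not tested. The probe of Bpifb9a lies on chromosome 10 from 44057416 to 44057475 in rn4. The array annotation describes its transcript as similar to Robo-1, so the name rests on the updated gene names alone. Of the 14 genes 13 lay in the 3 dimmest deciles of the genes tested. The count depends on scaling and background correction: quantile normalization called 0 genes higher and 1 lower (limma, 936 and 794 at an unadjusted p under 0.05), median centring 5 and 3, and normexp 0 and 0 (993 and 936). It was 1 without control replicate 1 or 2, 3 without TCDD replicate 2 or 4, 6 without TCDD replicate 3, 11 without control replicate 4, and 0 without control replicate 3 or TCDD replicate 1 (1554 and 1631 at an unadjusted p under 0.05).

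Other named genes stood apart between the groups without passing. Reg3b, a secreted lectin of the Reg family, was 3.66-fold higher (log2 1.87, SE 0.28, adjusted p = 0.10), and Mpo, the peroxidase of neutrophils, 1.65-fold higher (log2 0.73, SE 0.11, adjusted p = 0.090). Triml2, Pcnx2, Or4f61b and RT1-N3 were 1.46- to 1.67-fold higher. Slpi, a leukocyte protease inhibitor, was 2.22-fold lower (log2 -1.15, SE 0.20, adjusted p = 0.12), and the chemokine Cxcl2 1.93-fold lower (log2 -0.95, SE 0.14, adjusted p = 0.079). Fmo6, Syt8 and Or52e2 were well above background on all 4 control arrays and on 0 TCDD arrays, and were at least 1.64-, 1.33- and 1.40-fold lower. With normexp their fitted changes were -0.21, -0.04 and -0.07, and Reg3b stood at 1.16, Slpi at -0.59, Cxcl2 at -0.28 and Mpo at 0.23. Lcn5, Tesmin, Or4c122 and Pira2, the last well above background on 1 of 4 TCDD arrays, were 1.46- to 1.92-fold lower. The rule took these 15 genes because their 4 TCDD values lay all above or all below the 4 control values. That held for 1233 genes (7.10%), where chance alone gives 2.86% on average. The other splits of the arrays were not counted for this.

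At an unadjusted p under 0.05 there were 1860 genes, against a mean of 868 expected by chance and 1818 in the highest other of the 35 splits of the 8 arrays, with 1348 higher and 512 lower (72.5% higher). With quantile normalization the split was 936 higher and 794 lower (54.1% higher). Of the 1860 genes, 58 differed by at least 2-fold, 41 higher and 17 lower.

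**Figure D3:**
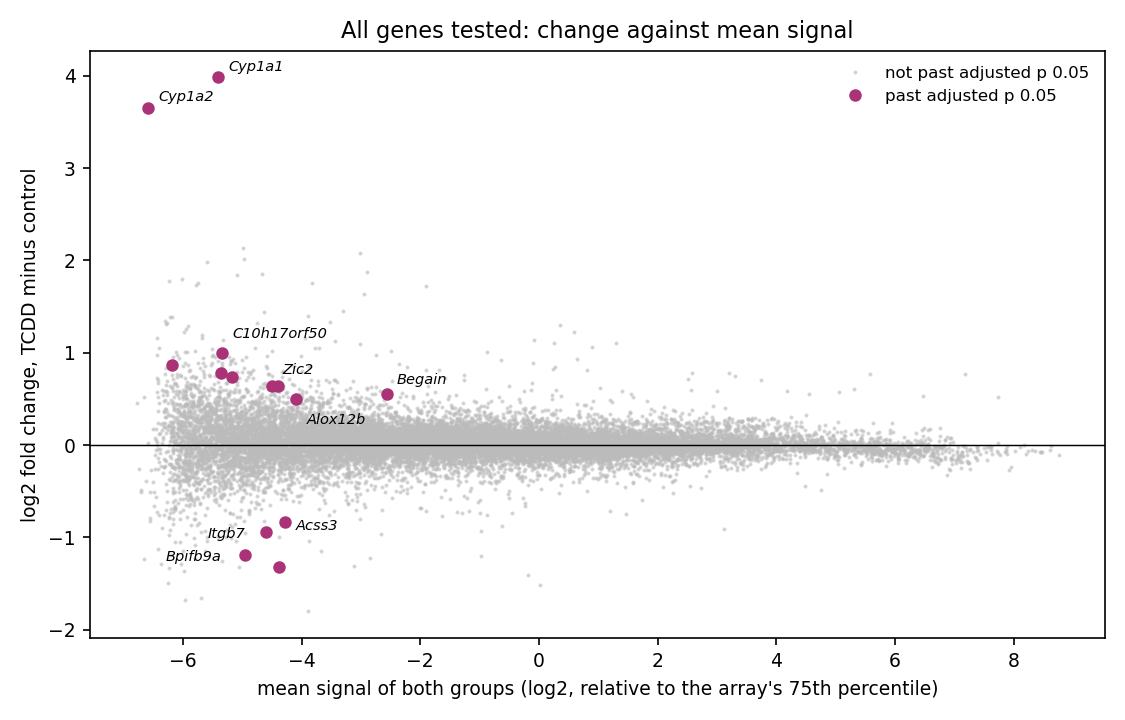
Log2 fold change (TCDD minus control) of all 17361 genes tested against the mean signal of both groups (log2, relative to the array's 75th percentile), with the 14 genes past an adjusted p of 0.05 as large points. Cyp1a1 and Cyp1a2 stand highest, at fitted changes of 3.98 and 3.65. No control array measured them above background, so these fitted changes are not used as sizes, and the text gives lower bounds instead.

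All 6 measured erythrocyte markers were higher, with a median log2 change of 0.65, and 6 passed adjusted over the list alone, though 0 over all genes. Slc4a1, the anion exchanger of the red cell membrane, rose 2.63-fold on that count (log2 1.39, SE 0.23; 0.68 with normexp), Alas2, the first enzyme of erythroid haem synthesis, 2.47-fold (log2 1.31, SE 0.36), and the globin genes Hbb-b1 and Hba-a1 1.70-fold and 1.44-fold. The list was shifted up (camera, adjusted p = 7.44e-05), a call lost with an estimated correlation (adjusted p = 0.61). Relative to the mean of the 8 arrays these markers stood at -0.41 ± 0.44 (SD, n = 4) in controls and 0.41 ± 0.29 (SD, n = 4) after TCDD, and control replicate 4, at 0.24, lay above TCDD replicate 1, at -0.01. Of 19 cell cycle genes 17 were higher (median log2 change 0.28), 0 of them past the threshold on either count. Examples are Tyms (log2 0.36, SE 0.09), Ccne1 (0.36, SE 0.13) and Aurkb (0.77, SE 0.28), at 0.25, 0.17 and 0.20 with normexp. Their list was shifted up (camera, adjusted p = 0.0019; adjusted p = 0.62 with an estimated correlation), which did not hold without control replicate 4 (adjusted p = 0.068).

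Another 3 lists were shifted down, each by a small amount, while the erythrocyte markers stood higher on the same arrays. Of 20 cytosolic ribosomal protein genes 17 were lower, with a median log2 change of -0.09 (camera, adjusted p = 0.0019; adjusted p = 0.72 with an estimated correlation). None of the 20 passed on either count, Rps23 standing at -0.27 (SE 0.09) by the probe used and at -0.06 by each of its 2 other probes, and the list did not pass with quantile normalization (adjusted p = 0.26), with normexp (0.31), without control replicate 4 (0.081) or without TCDD replicate 4 (0.055). Of 16 interferon response genes 13 were lower, with a median of -0.16 (camera, adjusted p = 0.018; adjusted p = 0.62 with an estimated correlation). Ifi27 differed by -0.49 (SE 0.18), Ifit3 by -0.72 (SE 0.31; -0.18 with normexp) and Isg15 by -0.41 (SE 0.19), while Oasl stood at 0.35 (SE 0.13), none past the threshold on either count. That list lost its call without control replicate 1, control replicate 4, TCDD replicate 2 or TCDD replicate 4 (adjusted p between 0.055 and 0.11). Of 12 glucocorticoid-responsive genes 9 were lower, with a median of -0.08 (camera, adjusted p = 0.0087; adjusted p = 0.61 with an estimated correlation). Errfi1, a feedback inhibitor of the EGF receptor, fell 1.25-fold (log2 -0.33, SE 0.06) adjusted over the list alone, and Klf9 and Fkbp5 stood at -0.26 (SE 0.09) and -0.35 (SE 0.16), while Mt1, a metallothionein, stood at 0.28 (SE 0.12). This list lost its call without TCDD replicate 4 (adjusted p = 0.061).

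**Figure D4:**
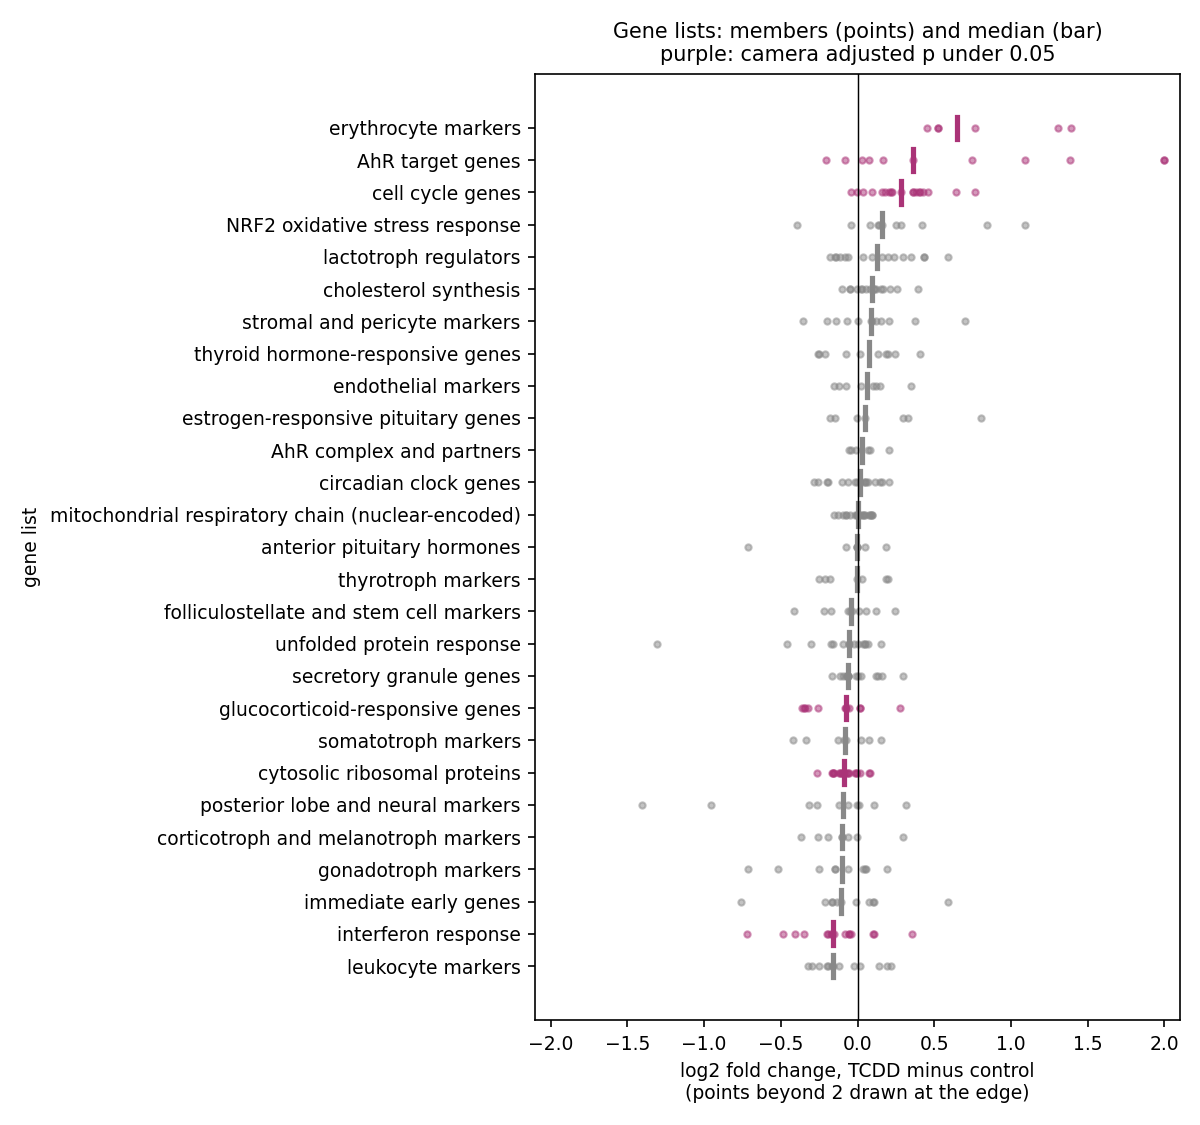
Log2 fold change (TCDD minus control) of the members of 27 gene lists (points, those beyond 2 drawn at the edge) with each list's median (bar), purple where camera gave an adjusted p under 0.05. The 6 purple lists include erythrocyte markers at a median of 0.65, AhR target genes at 0.36 and interferon response at -0.16, and with an estimated correlation 0 lists passed.

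The other 20 lists were not shifted by camera in the chosen settings, and neither were the hormones above. Among 11 genes of the NRF2 oxidative stress response 9 were higher (camera, adjusted p = 0.12; fry, adjusted p = 0.043). Adjusted over the list alone, Nqo1 rose and Srxn1, a sulfiredoxin, fell 1.32-fold (log2 -0.40, SE 0.11). Gpx2 stood at 0.84 (SE 0.33; 1.01 by its other probe) and Txnrd1 at 0.42 (SE 0.14; 0.09 by its other probe). Neither passed on either count. Of 16 lactotroph regulators, only Tgfb1 passed adjusted over the list alone, 1.35-fold higher (log2 0.43, SE 0.10; 0.15 with normexp), while Pou1f1, the pituitary transcription factor behind Prl and Gh1 expression, stood at 0.35 (SE 0.14) and did not pass. For the lists that mark pituitary cell types, camera's adjusted p was 0.12 for gonadotrophs, 0.34 for corticotrophs and melanotrophs, 0.28 for somatotrophs, 0.59 for thyrotrophs and 0.47 for folliculostellate and stem cells. It was 0.17 for the posterior lobe and neural tissue, 0.59 for endothelium, 0.96 for stroma and pericytes, and 0.12 for leukocytes. Avp, the vasopressin gene of the posterior lobe, stood at -1.41 (SE 0.52, adjusted p = 0.41), with a control SD of 1.04. Some of these lists passed as lower when 1 array was left out: posterior lobe and neural markers without control replicate 4 (adjusted p = 0.0013) or TCDD replicate 3 (0.040), gonadotroph markers without control replicate 4 (0.030), and leukocyte markers without control replicate 3 (0.017), TCDD replicate 1 (0.016) or TCDD replicate 3 (0.022).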

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

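The comparison of 8 AhR target genes with random lists was chosen after the result was seen. The values in this part that set an array apart come from Dixon's ratio of the gap to the range within a group of 4 arrays. Over 280 such groups 12 stood out, where chance gives about 5%. That is no more than chance gives, so single entries below may reflect chance alone. In the TCDD group these were Arnt on replicate 4 (0.888), Pgr on replicate 1 (0.890), Dio2 on replicate 2 (0.853) and Plvap on replicate 4 (0.839). In the control group they were Cxcl2 and Btg2 on replicate 3 (0.998 and 0.919). Control replicate 4 stood out for the other 6 of the 12: Inha (0.908), Gata2 (0.907), Ptgds (0.848), Hbb-b1 (0.863), and the first and second principal components (0.888 and 0.958). On that array, relative to the mean of the 8, posterior lobe and neural markers stood at -0.55, stromal and pericyte markers at -0.52 and erythrocyte markers at 0.24. Posterior lobe and neural markers varied widely on other arrays too. TCDD replicate 2 stood at -0.46 for them, and control replicates 2 and 3 at 0.51 and 0.42.

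AhR target genes were higher on the TCDD arrays. For the 11 measured members the median log2 change of 0.36 lay at percentile 100 of 10000 random lists matched on mean signal. The highest median of those lists was 0.31, so genes of like mean signal did not rise as much in general. Cyp1a1, Cyp1a2 and Ahrr passed the filter through the TCDD arrays alone, and the random lists were not matched on that. A general shift of dim signals on slide 2 is therefore not excluded by this comparison. The median of 0.12 of the 8 members other than Cyp1a1, Cyp1a2 and Ahrr, at percentile 95.01, decides nothing, since a rise from below background itself sets which members are left out. Liver RNA is argued against, as of 12 abundant liver transcripts 8, Alb included, were above background on no array. Those above background on all 8 arrays were Ahsg at -0.09, Apoa2 at 0.03 and Apoc3 at -0.53. Apoa1, above background on 5 arrays, stood at 0.52 (SE 0.53). The 12 had a median change of 0.021 and a highest of 0.58, though most of them gave no signal above background. An induction by TCDD remains a hypothesis, since a difference between the slides that acts on these genes alone cannot be excluded by the design.

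Erythrocyte markers were higher on the TCDD arrays. Within groups their deviations moved together over the arrays (median correlation 0.94 over 15 pairs of genes), which is consistent with red blood cell content that varies between animals. Their median lay at percentile 100 of 10000 random lists matched on mean signal. Those lists had a middle median of -0.03 and a highest of 0.21, so genes of like signal did not rise as much in general. Their members were drawn independently, whereas these markers move together. A difference between the slides that acts on these markers is therefore not excluded. Chance is not excluded: 2 of the 35 splits of the 8 arrays gave a median as large as 0.65, the highest other split reaching 0.84. Whether TCDD changed the blood content was not tested apart from this.

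More genes were higher than lower on the TCDD arrays. This may come from scaling by the 75th percentile: with quantile normalization 54.1% of the genes at an unadjusted p under 0.05 were higher, in place of 72.5%. The median change was 0.06 in the dimmest decile of genes and -0.01 in the brightest. Quantile normalization gives every array the same distribution and would remove a true excess of rises too, so such an excess remains open.

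For the count of 14 genes 1 of the 35 splits, the real one, gave as many, and the highest other split gave 5. For the 10 higher genes it was 1 of 35 as well, with 5 as the highest other. That is the smallest share 35 splits can give, so it argues against a chance arrangement of the arrays without excluding it. The splits were counted in the chosen settings alone. There the count was 14, and it was 1 with quantile normalization and 0 with normexp. At an unadjusted p under 0.05 the highest other split gave 1818 genes, against 1860 in the real one. For the 4 lower genes chance is not excluded, since 2 of 35 splits gave as many in 1 direction, with 5 as the highest other. For the 6 shifted lists it is not excluded either, since 7 of 35 splits gave as many, with 11 as the highest other.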

How the results depend on the processing

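Of the 14 genes called (10 higher, 4 lower), none of the 9 with a symbol turned its direction under the settings run, and the 5 without a symbol were not followed over them. Named genes near 0 that did not pass, such as Prl, Pomc, Cga, Lhb and Tshb, took either sign. Of the comparisons of named genes with an alternative 2650 stayed on their side of the threshold, 120 lost a call and 13 gained one, and of those of lists 552, 26 and 17. Most of the 2650 are of genes not called, and all 120 lost calls are of the 9. Normexp with quantile normalization gave 0 genes (0 higher, 0 lower; limma, 1929 at an unadjusted p under 0.05). Quantile normalization and the deposited table each gave 1 (0 higher, 1 lower). Median centring gave 8 (5 higher), eBayes with trend and robust 4 (2 higher, 2 lower), array weights 30 (20 higher, 10 lower) and every probe tested on its own 9 (6 higher). Without the filter on dim probes 13 were called, 7 of them among the 14. An unadjusted p under 0.05 with at least 2-fold gave 58. Without the 2 arrays farthest out on the first principal component, chosen after seeing the data, it was 5 (3 higher, 2 lower) and 11 lists in place of 6. Lists that gained a call there were anterior pituitary hormones, somatotroph markers, thyrotroph markers and folliculostellate and stem cell markers (adjusted p = 0.042 each), gonadotroph markers (0.036), the NRF2 oxidative stress response (0.048) and posterior lobe and neural markers. Cell cycle genes (0.059) and the interferon response (0.20) lost theirs. The NRF2 list also passed with normexp (0.032) and by fry (0.043), posterior lobe and neural markers with array weights (0.013), and the unfolded protein response without TCDD replicate 2 (0.021). Estimated correlation gave 0 lists and fry 2. The causes were not tested.

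Leaving out 1 array gave 0 to 11 genes, 0 to 9 higher, 0 to 3 lower, and 3 to 8 lists. The gene count was 1 without control replicate 1, 1 without control replicate 2, 0 without control replicate 3, 11 without control replicate 4 (6 shared with the 14), 0 without TCDD replicate 1, 3 without TCDD replicate 2, 6 without TCDD replicate 3 and 3 without TCDD replicate 4. Fewer samples enter these fits. Over the alternatives Cyp1a1 had an adjusted p between 0.020 and 0.32 and Cyp1a2 the same, past the threshold in 9 of 20 each, Bpifb9a in 17 of 21, C10h17orf50 and Acss3 in 7, Itgb7 in 6, Zic2 in 5, Begain in 4 and Alox12b in 3. The fitted change lay between 1.04, with normexp, and 4.21 for Cyp1a1 and between 0.57 and 4.00 for Cyp1a2. The list of AhR target genes passed in 20 of 23.

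With the replicate number as a block (replicate block) 0 genes were called (0 higher, 0 lower; limma, 1514 at an unadjusted p under 0.05) and 6 lists. The numbers are positions on the slide. Deviations of same-numbered arrays correlated at -0.02, -0.07, -0.03 and -0.10, and no control array correlated best with the TCDD array of its own number. These correlations over all genes showed no pairing. They cannot exclude an effect of slide position on single genes. Signal over background limits the dim genes: 13 of the 14 calls lie in the 3 dimmest deciles. A fit with slide as a block was not run, since each slide holds 1 group.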

Other observations

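The test of bone marrow in this part was chosen after the erythrocyte markers had been seen, and before its own genes were looked at. Cholesterol synthesis genes were higher in 12 of 16 (camera, adjusted p = 0.20), with Mvd at a log2 change of 0.21 (SE 0.06), and unfolded protein response genes lower in 9 of 15 (adjusted p = 0.18), with Atf4 at -0.30 (SE 0.13) and Trib3 at -1.31 (SE 0.60). Secretory granule genes (adjusted p = 0.47), circadian clock genes (0.81), immediate early genes (0.41), estrogen-responsive genes (0.81), thyroid hormone-responsive genes (0.81), the nuclear-encoded respiratory chain (0.59) and the AhR complex (0.99) did not pass camera either. The AhR complex and the thyroid hormone-responsive list have a median above 0 and a camera direction below the other genes, and the clock and respiratory chain lists a median above 0 and a mean below it.

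Higher erythrocyte and cell cycle genes, with Mpo at 0.73, raise the hypothesis that bone marrow cells may be in the tissue. It predicts granulocyte precursor genes on the same arrays. Of 10 such genes 9 were not well above background on enough arrays to be tested, 7 of them on no array, and the remaining 1, Camp, differed by 0.03 (SE 0.14). Mpo, which helped raise the hypothesis, was not among the 10. The outcome rests mostly on probes without signal. It goes against a large share of marrow cells as the source only if those probes detect marrow RNA. Genes near background and probes not tested on marrow limit what it excludes, and a small share stays open.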
